A study of Rattus norvegicus with 6 samples.

How the data were processed

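RNA was sequenced from the ventral hippocampus of 6 male rats, 3 adult and 3 aged, each library from a separate animal. The count values were deposited by the authors as raw counts per gene symbol, with a column per library, and the values were whole numbers. The authors also deposited FPKM values, and each gene's FPKM was found to be its count divided by a fixed gene length and by the library total, so both tables hold the same measurement. Reads were mapped to the rat genome build Rnor_6.0, per the submitters' processing notes. The aligner, the counting program, its annotation and its use of strand are not given in the sources used here. In the table, 27 symbols had been turned into dates, 2 of them repeated, and these were kept as they stand.

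Library totals lay between 12476758 and 15689921 counts. Genes were matched by symbol to an annotation of another assembly, GRCr8, used only for names and for overlapping or adjoining genes, and 14148 (97.0%) of the genes tested and 20371 of the table's 22601 were matched.

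The comparison was aged minus adult, with age as the only term. Genes were filtered with edgeR's filterByExpr, which left 14588, scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest, edgeR 4.0.16 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are scaled by TMM, except that the sums of liver and muscle genes, and the values of Alb and Pygm given with them, are CPM of the library total. Means are given with SD over 3 rats, and intervals and tests rest on the variation between only these 6 animals.

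Of 47 gene lists written before the data were examined, holding 944 genes of which 895 were in the table, 45 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Adjusted p-values of lists are from limma's camera or, where named, its fry. List scores per library were compared by exact two-sided permutation tests, which cannot go below 0.1 with 3 rats against 3. The test of single genes, the lists, the alternatives planned and the rule for naming genes were also fixed before the data were examined. That rule took, in each direction, the 12 called genes with the smallest p among genes with a mean of at least 1 CPM, a symbol other than a locus identifier and groups that did not overlap, filled to 6 by the smallest p where fewer were called. It took up to 4 called members of each list, or the 2 with the smallest p in a list with no call that the text describes, and Gfap, Cd74, C3, Dcx, Ttr, Bdnf, Fos and Mbp in every case. Some genes that the rule takes are not reported here. Genes outside this rule are said to be chosen by their calls or values.

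Other settings, also chosen in advance, were RLE, upper-quartile and library size scaling, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust quasi-likelihood, limma on log2 FPKM with pseudocounts of 1 and 0.1 and with no filter, other thresholds, the replicate number as a block, leaving out each library, and for lists an estimated correlation, fry and a prior count of 0.5. Chosen after seeing the data were 1 surrogate variable (sva 3.50.0), a block for the libraries with low liver transcripts, and leaving out genes that differed at least 8-fold between libraries of one age. The scripts were tested on simulated counts of 14412 genes in the same design. For aged against adult, edgeR called 4.00% of genes changed 1.5-fold, 46.0% at 2-fold, 81.6% at 4-fold and 93.9% at 8-fold, with 7 of 14214 unchanged genes called, and both shifted lists and 0 other lists were called. Counts were drawn independently for each gene, with changed genes at a mean of at least 1 CPM and 2 lists shifted by 1 log2 unit. Differences shared by many genes of a library were therefore absent. The list result does not cover false calls by camera where members of a list vary together. Figures were drawn with matplotlib 3.10.9. Water maze results and genes encoded by the mitochondrial genome were not analysed here.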

Results

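RNA was sequenced from the ventral hippocampus of male Sprague Dawley rats, an outbred laboratory strain, at 4 months of age (adult) and 22 months of age (aged). Each age group held 10 rats tested in the Morris water maze, a spatial memory task in a pool with a hidden platform, and 3 rats of each group were drawn at random for sequencing, so each of the 6 libraries came from a separate animal. The deposited table held read counts for 22601 genes. Library totals were 14637811, 15689921 and 15427497 counts in adult replicates 1 to 3 and 15327486, 12476758 and 15400405 counts in aged replicates 1 to 3. The comparison asked how the hippocampal transcriptome of aged rats differed from that of adult rats.

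The libraries did not separate by age along the leading components of expression. The first principal component held 28.7% of the variance and placed adult replicate 1 (-41.7) and aged replicate 2 (-23.2) at the same end, with adult replicates 2 and 3 at 27.7 and 28.3. On the second (22.6%), aged replicates 1 (40.5) and 3 (13.1) lay above every adult library. Aged replicate 2 (-16.7) lay within the adult range of -30.5 to 0.0046 there. The median Spearman correlation was 0.978 over the 6 pairs of libraries of the same age and 0.979 over the 9 pairs of different ages. The biological coefficient of variation estimated by edgeR was 23.4%.

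**Figure D1:**
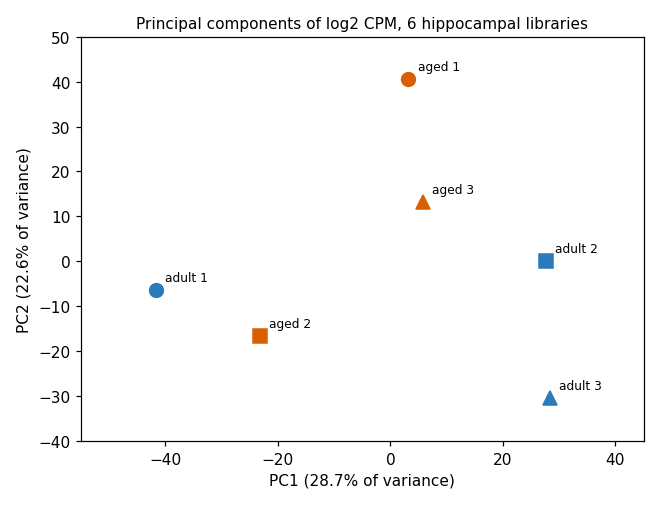
Principal components of log2 CPM for the 6 libraries, with PC1 (28.7% of the variance) on the x axis and PC2 (22.6%) on the y axis, adult rats in blue and aged rats in orange. Adult replicate 1 lies at -41.7 and adult replicate 3 at 28.3 on PC1, so on that axis the 3 adult libraries span the range of the aged ones. On PC2 aged replicates 1 and 3 lie above the adult libraries, and aged replicate 2 lies within their range.

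Several libraries stood apart through transcripts of other tissues. Adult replicate 1 carried choroid plexus RNA: Ttr, which encodes the transthyretin secreted by that epithelium, stood at 2076 CPM there and between 4.39 and 68.0 CPM in the other 5 libraries. Transcripts of liver were low in replicate 1 of both ages and higher in the other 4 libraries. The 41 liver genes looked up summed to 72.3 and 74.0 CPM of the library total in adult and aged replicate 1, to 848 and 869 in adult replicates 2 and 3, and to 437 and 353 in aged replicates 2 and 3, with albumin (Alb) alone at 434 in adult replicate 2. The 22 skeletal muscle genes summed to 336, 342 and 832 CPM in adult replicates 1 to 3 and to 324, 176 and 249 CPM in aged replicates 1 to 3. Pygm, a muscle phosphorylase that astrocytes also express, stood between 79.9 and 107 CPM in all 6 libraries. The liver and muscle genes were picked after these transcripts had been seen in the data.

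**Figure D2:**
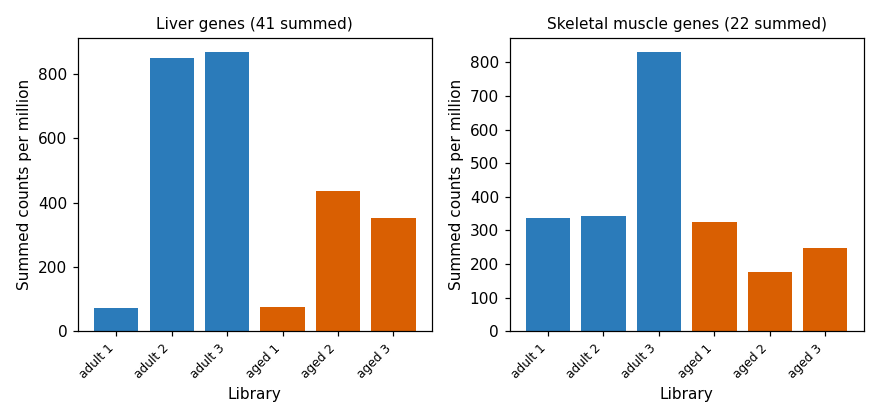
Summed CPM (of the library total) of 41 liver genes (left) and 22 skeletal muscle genes (right) in each library, with adult rats in blue and aged rats in orange. Liver genes were at 72.3 and 74.0 in replicate 1 of each age and between 353 and 869 in the other 4 libraries, and muscle genes were highest (832) in adult replicate 3.

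Between the ages, lists of myelin, vessel wall and meningeal fibroblast genes were called lower in aged rats, and lists of MHC class II antigen presentation and immediate early genes were called higher, while no individual gene passed the threshold. These calls were made by camera with a preset inter-gene correlation, and 0 lists were called with an estimated correlation (smallest adjusted p = 0.469) or by fry (smallest adjusted p = 0.580). Mbp, which encodes myelin basic protein, averaged 8398 ± 2226 CPM in adult and 4693 ± 676 CPM in aged rats (SD, n = 3), and Cd74, the invariant chain of MHC class II, averaged 15.8 ± 4.30 and 43.1 ± 23.4 CPM. Gfap, the intermediate filament of astrocytes, averaged 842 ± 61.6 and 818 ± 210 CPM, and the complement component C3 averaged 39.6 ± 13.6 and 40.9 ± 7.38 CPM.

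Of 14588 genes tested with edgeR's quasi-likelihood test, 0 were called at an adjusted p under 0.05 (Benjamini-Hochberg), 0 higher and 0 lower in aged rats, and the smallest adjusted p was 0.510. At an unadjusted p under 0.05 there were 503 genes, 172 higher and 331 lower, where about 729 would be expected with no effect. Of these, 169 differed at least 2-fold, 73 higher and 96 lower in aged rats. DESeq2 called 32 genes, 13 higher and 19 lower, limma-voom called 0, and limma on log2(FPKM + 1) called 1, Polr2i. The DESeq2 calls included locus identifiers such as LOC100912599 (DESeq2 adjusted p = 9.88e-09), named for its call. They also included LOC103690005, LOC100911959 and Mff, named because they differed at least 8-fold between libraries of one age. In 1103 genes (7.56%) the 3 adult and 3 aged values did not overlap, against 10% by chance. On simulated counts of the same design, edgeR called 46.0% of genes changed 2-fold and 81.6% of genes changed 4-fold. Those counts were drawn independently for each gene, without patterns shared by many genes of a library. The shares may therefore not hold for the real libraries. Without adult replicate 1, 2 or 3, edgeR called 1 gene each time, which was Mff, Tma7 and LOC103690005 in turn, all lower in aged rats and named here because they were the genes called. Each was low in the library left out, with Mff at 1.84 CPM in adult replicate 1, Tma7 at 6.83 CPM in adult replicate 2 and LOC103690005 at 1.27 CPM in adult replicate 3. Tma7 overlaps Ccdc51 in the GRCr8 annotation. Genes at an unadjusted p under 0.05 and at least 2-fold numbered 302 without adult replicate 1 and 280 without adult replicate 2.

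The genes with the smallest p were taken by the naming rule, which leaves out locus identifiers. Among those that stood higher in aged rats, none passed the threshold (edgeR quasi-likelihood, Benjamini-Hochberg). Cdh23, a cadherin of hair cell tip links, averaged 3.79 ± 0.284 CPM in adult and 11.1 ± 1.26 CPM in aged rats, a log2 fold change of 1.55 ± 0.21 (SE) with an adjusted p of 0.510 by edgeR. Eqtn averaged 1.63 ± 0.330 and 5.79 ± 1.16 CPM, and Cdh1, which encodes E-cadherin, averaged 0.700 ± 0.177 and 3.05 ± 0.355 CPM. Cd4, a co-receptor of helper T cells that rat microglia also express, averaged 5.93 ± 1.04 and 13.5 ± 2.78 CPM. Ciart, a repressor in the circadian clock, averaged 6.59 ± 0.483 and 11.6 ± 1.47 CPM. Atp5f1, a subunit of ATP synthase, averaged 2.12 ± 0.729 and 12.4 ± 8.18 CPM. In the GRCr8 annotation Cdh23 overlaps Psap, Vsir and C20h10orf105, and Eqtn overlaps Mysm1, so their counts are uncertain where reads were not assigned by strand.

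Among those that stood lower, Polr2i, a subunit of RNA polymerase II, averaged 7.01 ± 2.53 CPM in adult and 0.174 ± 0.162 CPM in aged rats. Its log2 fold change was -5.34 ± 0.70 with an adjusted p of 0.510 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Whether its near absence in aged rats comes from how reads were assigned was not tested. The selenoprotein gene Sepw1 averaged 97.6 ± 30.6 and 36.1 ± 3.90 CPM, and the transglutaminase gene Tgm2 averaged 23.7 ± 2.72 and 11.9 ± 0.915 CPM. Tnfaip6, which encodes a hyaluronan-binding protein, averaged 6.39 ± 1.26 and 1.35 ± 0.624 CPM. Pnlip, a lipase gene, averaged 9.35 ± 1.27 and 3.78 ± 0.249 CPM. Dio2, the deiodinase that activates thyroid hormone, averaged 48.7 ± 3.83 and 31.1 ± 1.04 CPM. DESeq2 called 11 of these 12 genes, the exception being Ciart. The 12 were picked by their edgeR p in the same libraries, so the DESeq2 calls are not separate evidence.

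**Figure D3:**
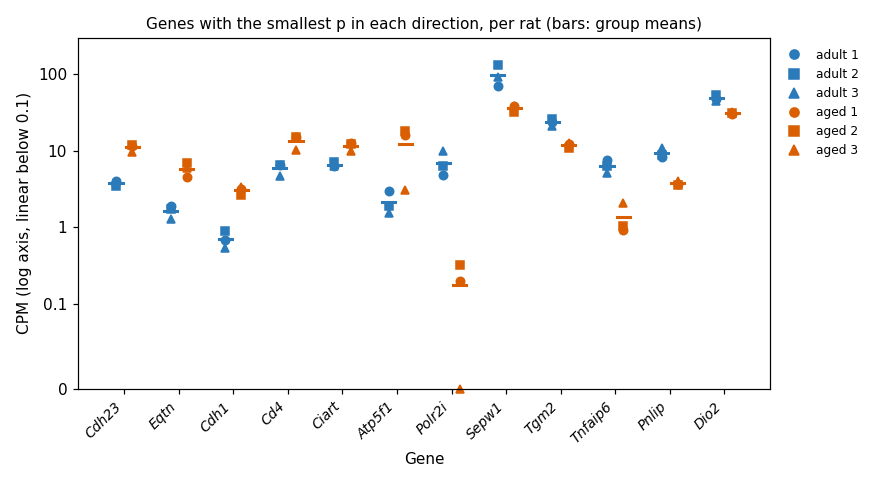
CPM per rat of the 6 genes with the smallest p in each direction among genes with a mean of at least 1 CPM, a symbol other than a locus identifier and groups that did not overlap. The axis is logarithmic and linear below 0.1, with adult rats in blue, aged rats in orange and short bars at the group means. Polr2i lies between 4.85 and 9.80 CPM in adult rats and at or below 0.321 CPM in aged rats, and none of the 12 genes passed the adjusted threshold.

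Gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation, with Benjamini-Hochberg adjustment over the 45 lists with at least 5 tested members. Of these, 16 were called, 10 lower and 6 higher in aged rats. With an estimated correlation 0 lists were called by camera (3 at an unadjusted p under 0.05, smallest adjusted p = 0.469), and fry called 0 (3 at an unadjusted p under 0.05, smallest adjusted p = 0.580). Exact two-sided permutation tests of list scores gave p = 0.1 for immediate early, endothelium, pericyte and meningeal fibroblast lists. The same exact permutation test gave p = 0.2 for myelin, MHC class II, proliferation and collagen lists. Synaptic vesicle, interneuron, monoamine receptor and blood lists had p = 0.3 by exact permutation test. Ribosome and neocortex lists had p = 0.4, oligodendrocyte precursors 0.5 and choroid plexus 0.6 by exact permutation test. Over all genes tested, 0 members of any list were called by edgeR, so every member named is given by its values.

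**Figure D4:**
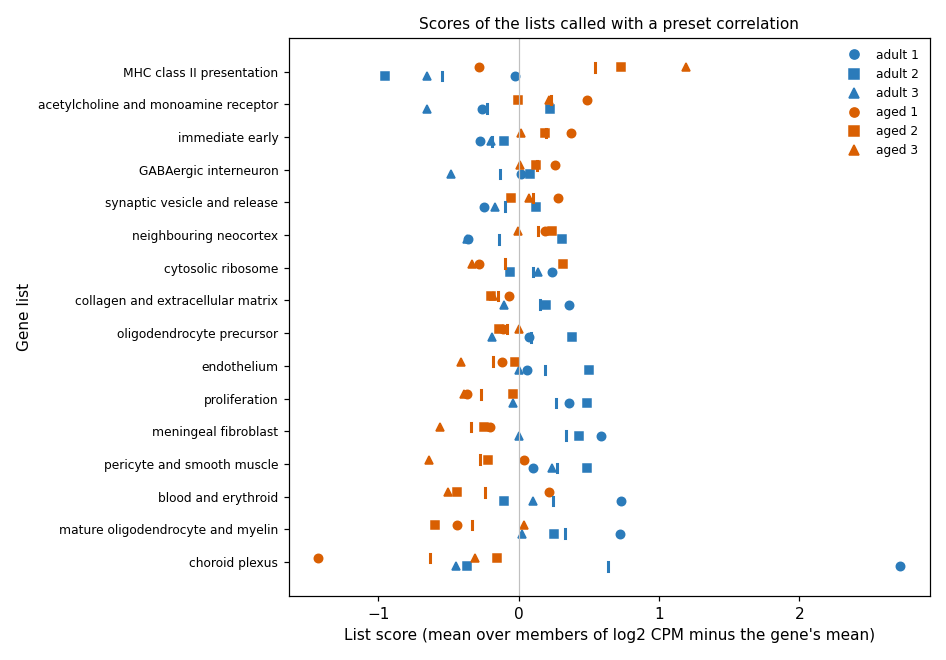
Score per library of the 16 lists called with a preset correlation, as the mean over members of log2 CPM minus the gene's mean over the 6 libraries on the x axis and the lists on the y axis, with adult rats in blue, aged rats in orange and short bars at the group means. Scores of the immediate early, endothelium, pericyte and smooth muscle, and meningeal fibroblast lists do not overlap between the ages, and the choroid plexus score of adult replicate 1 is 2.72.

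Genes of mature oligodendrocytes and myelin, the insulating sheath around axons, were lower in aged rats. Of 19 members tested, 18 had lower values, with a median log2 fold change of -0.67, and 11 were called by edgeR when adjusted over the list alone, against 0 over all genes. The camera adjusted p was 2.16e-15, and adjusted p = 0.517 with an estimated correlation. Ugt8, which makes the myelin lipid galactosylceramide, averaged 119.7 ± 30.5 CPM in adult and 63.9 ± 7.46 CPM in aged rats. The log2 fold change of Mbp was -0.84 ± 0.21 (SE), with 3 of 3 aged rats below every adult rat, and DESeq2 called Mbp and Ugt8. The list score was highest in adult replicate 1 (0.718) and aged replicate 3 (0.040) lay above adult replicate 3 (0.025). Adjusted over the list alone, the count of 11 became 0 without adult replicate 1, aged replicate 1 or aged replicate 2, 17 without aged replicate 3 and 5 with unfiltered FPKM. Oligodendrocyte precursor genes had 12 of 16 members lower (median -0.18, camera adjusted p = 0.00995, adjusted p = 0.623 with an estimated correlation), 0 of them called when adjusted over the list alone. Among them Bmp4 averaged 13.9 ± 0.244 and 8.80 ± 1.62 CPM and the lineage factor Olig2 averaged 44.7 ± 8.42 and 33.3 ± 2.64 CPM. That call ended without adult replicate 1 (adjusted p = 0.108), adult replicate 2 (0.473) or aged replicate 1 (0.0633).

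Vessel wall and meningeal transcripts were lower in aged rats. Pericyte and smooth muscle genes had 15 of 16 members lower (median -0.57, camera adjusted p = 1.26e-08, adjusted p = 0.517 with an estimated correlation), with 0 called when adjusted over the list alone. Vtn averaged 42.1 ± 6.95 CPM in adult and 26.5 ± 7.49 CPM in aged rats, and the peptidase gene Anpep averaged 6.04 ± 1.40 and 3.46 ± 0.213 CPM. All 18 endothelial genes were lower (median -0.385, camera adjusted p = 1.53e-07, adjusted p = 0.581 with an estimated correlation), with 0 called when adjusted over the list alone. Among them the thyroid hormone and anion transporter gene Slco1c1 averaged 123.8 ± 14.6 and 92.6 ± 14.4 CPM and the receptor gene Tie1 averaged 27.9 ± 6.30 and 18.0 ± 3.39 CPM. Without aged replicate 3 the pericyte median was -0.35, and 2 pericyte members were called over the list alone without aged replicate 1 and 1 without aged replicate 2. Exact two-sided permutation tests of the scores of these lists each gave p = 0.1, the smallest p that 3 rats against 3 allow (adjusted p = 0.926 over 45 lists).

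Meningeal fibroblast genes had 15 of 18 members lower (median -0.47, camera adjusted p = 1.26e-08, adjusted p = 0.469 with an estimated correlation), and 6 were called by edgeR when adjusted over the list alone. Col1a2, a chain of fibrillar collagen I, averaged 9.07 ± 5.43 CPM in adult and 1.67 ± 0.445 CPM in aged rats, and the growth factor gene Igf2 averaged 82.2 ± 53.6 and 22.0 ± 7.47 CPM, and DESeq2 called both. Igf2 stood at 144 CPM in adult replicate 1, and without that library its log2 fold change of -1.90 became -1.21. The 6 members called over the list alone fell to 2 without adult replicate 1, adult replicate 2 or aged replicate 2 and to 3 without aged replicate 1. Igf2 overlaps LOC102548568 in the GRCr8 annotation, so its count is uncertain where reads were not assigned by strand. Collagen and extracellular matrix genes, which share Col1a2 with that list, had 19 of 27 members lower (median -0.15, camera adjusted p = 0.00246, adjusted p = 0.517 with an estimated correlation), 2 of them called when adjusted over the list alone, Col1a2 and Bgn. The proteoglycan gene Bgn averaged 42.6 ± 1.44 and 22.6 ± 7.48 CPM. The list's call ended without adult replicate 1 (adjusted p = 0.202), and its median was -0.24 without adult replicate 3 and -0.30 without aged replicate 3. The 2 members called when adjusted over the list alone became 1 without adult replicate 2, 4 without aged replicate 1 or with limma-voom or log2(FPKM + 1), and 5 with DESeq2. They became 0 without aged replicate 2 or aged replicate 3 and with unfiltered FPKM.

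Choroid plexus and blood transcripts were lower in aged rats, with adult replicate 1 standing highest for both. All 10 choroid plexus genes tested were lower (median -1.99, camera adjusted p = 0.000867, adjusted p = 0.629 with an estimated correlation), with 0 called when adjusted over the list alone. The water channel gene Aqp1 averaged 9.14 ± 6.73 CPM in adult and 2.95 ± 1.37 CPM in aged rats, and F5 averaged 4.15 ± 4.82 and 0.436 ± 0.368 CPM. Ttr averaged 712 ± 1181 and 38.0 ± 31.9 CPM, and its log2 fold change of -4.23 became 0.33 without adult replicate 1. Without that library the median of the list was -0.02 and its adjusted p 0.783. Adjusted over the list alone, 5 members were called without adult replicate 2 or with DESeq2, 7 without adult replicate 3, 2 without genes that differed at least 8-fold between libraries of one age, and 1 with the block for liver transcripts or the surrogate variable. Blood and erythroid genes had 8 of 9 members lower (median -0.63, camera adjusted p = 0.00272, adjusted p = 0.629 with an estimated correlation), 0 called when adjusted over the list alone. The haemoglobin genes Hba-a1 and Hbb-b1 averaged 6.07 ± 0.478 and 33.0 ± 12.4 CPM in adult and 2.89 ± 1.02 and 19.7 ± 4.76 CPM in aged rats. That call ended without adult replicate 1 (adjusted p = 0.400, median -0.19), aged replicate 2 (0.169) or aged replicate 3 (0.160). The count adjusted over that list alone was 1 without aged replicate 1 and with DESeq2, limma-voom or FPKM values, and 2 with the block for liver transcripts. Genes of the ependyma and motile cilia had 4 members higher and 11 lower (median -0.125, camera direction higher, adjusted p = 0.969), and without adult replicate 1 the median was 0.69 and the adjusted p 0.00315, and without aged replicate 1 the median was 0.175.

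Genes of proliferation and of cytosolic ribosomes were called lower in aged rats by camera with the preset correlation. Proliferation genes had 13 of 16 members lower (median -0.41, camera adjusted p = 4.24e-06, adjusted p = 0.469 with an estimated correlation), with 0 called when adjusted over the list alone. Top2a averaged 1.55 ± 0.706 CPM in adult and 0.373 ± 0.332 CPM in aged rats and the kinase gene Cdk1 0.900 ± 0.106 and 0.276 ± 0.110 CPM. The call ended under a filter of at least 1 CPM in 3 libraries (adjusted p = 0.109), the median was -0.26 without adult replicate 2, and 1 member was called over the list alone with unfiltered FPKM. All 36 ribosomal protein genes were lower (median -0.15, camera adjusted p = 0.000171, adjusted p = 0.843 with an estimated correlation), with 0 called when adjusted over the list alone. Rpl30 averaged 232.6 ± 37.8 and 168.0 ± 23.2 CPM and Rps28 averaged 151.3 ± 45.8 and 113.5 ± 26.8 CPM. The ribosomal score did not follow age. It was above 0 in aged replicate 2 (0.317) and adult replicates 1 (0.234) and 3 (0.134). It was below 0 in adult replicate 2 (-0.0634) and aged replicates 1 (-0.284) and 3 (-0.337). The camera call ended without adult replicate 1 (adjusted p = 0.238), aged replicate 1 (0.223) or aged replicate 3 (0.511). The ribosomal median was -0.0379, -0.0468 and -0.0432 without these libraries in turn, -0.23 without adult replicate 2 and -0.37 without aged replicate 2. Over all genes the log2 fold change rose weakly with gene length (Spearman correlation 0.115), and its fitted trend ran from -0.29 to 0.00785. Rpl30 and Rps28 are short (464 and 339 bases), and the ribosomal median lies within that range. Gene length was weighed for the myelin list only, so a length bias stays open here.

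MHC class II presentation, by which antigen-presenting cells such as microglia show peptides to T cells, was higher in aged rats. All 6 members tested, of 12 in the table, were higher (median 1.375, camera adjusted p = 3.27e-06, adjusted p = 0.517 with an estimated correlation), and 6 were called by edgeR when adjusted over the list alone. Those 6 members shared a single edgeR adjusted p of 0.0490, set by RT1-Db1, so they passed together. Cd74 stood at 17.2 CPM in aged replicate 1, within the adult range of 12.9 to 20.8 CPM, and at 49.4 and 62.6 CPM in aged replicates 2 and 3. The protease gene Ctss averaged 172.4 ± 31.3 and 244.6 ± 41.5 CPM. The count adjusted over the list alone was 4 without adult replicate 1 and 0 without adult replicate 2, adult replicate 3, aged replicate 2 or aged replicate 3, and the median was 0.74 without aged replicate 3. That count was also 0 without a filter, with limma-voom, FPKM values or the block for liver transcripts, and 2 with DESeq2.

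Other immune and glial lists were not called. Homeostatic microglia had 12 of 15 members higher (median 0.175, adjusted p = 0.119), with P2ry12, a purinergic receptor of resting microglia, at 21.6 ± 3.39 CPM in adult and 31.6 ± 9.26 CPM in aged rats. P2ry12 overlaps Med12l in the GRCr8 annotation, so its count is uncertain where reads were not assigned by strand. Activated microglia had 14 of 18 higher (median 0.12, adjusted p = 0.228). The lipid receptor gene Trem2 averaged 10.5 ± 3.49 and 17.8 ± 3.68 CPM, and Cd9, which oligodendrocytes also express, averaged 106.2 ± 26.9 and 61.7 ± 5.42 CPM and was the 1 member called when adjusted over the list alone, in the direction opposite to the list. That count was 0 without adult replicate 1, adult replicate 3 or any aged replicate, with RLE, upper-quartile or library size scaling, with at least 1 CPM in 3 libraries, with limma-voom or FPKM values, and with the block for liver transcripts. Complement had 9 of 16 members lower (median -0.14, adjusted p = 0.270), with C1s at 12.9 ± 1.41 and 9.24 ± 1.28 CPM and Serping1 at 15.5 ± 0.846 and 11.2 ± 0.409 CPM. Interferon response genes had 22 of 34 lower (median -0.08, adjusted p = 0.108), with Bst2 at 8.27 ± 0.697 and 4.07 ± 1.76 CPM and Ifitm3 at 17.1 ± 1.69 and 11.6 ± 3.06 CPM. Astrocyte genes had 10 of 16 lower (median -0.04, adjusted p = 0.270), with Aldh1l1 at 31.3 ± 2.60 and 26.1 ± 4.83 CPM and Sox9 at 42.0 ± 7.41 and 29.7 ± 1.70 CPM. Reactive astrocyte genes had 15 of 23 lower (median -0.07, adjusted p = 0.261), with Serpina3n at 14.9 ± 4.11 and 5.32 ± 1.40 CPM, the 1 member called when adjusted over the list alone, and Aspg at 1.51 ± 0.502 and 3.82 ± 0.832 CPM. The count adjusted over that list alone was 0 without adult replicate 1, adult replicate 3, aged replicate 1 or aged replicate 3, and 2 with DESeq2, unfiltered FPKM or the block for liver transcripts. MHC class I (median -0.07, adjusted p = 0.495), inflammatory cytokines and chemokines (0.02, 0.786) and perivascular macrophages (-0.22, 0.367) were not called either. Medians crossed 0 without aged replicate 3 for complement (0.03), interferon response (0.06) and MHC class I (0.02), and without adult replicate 2 (0.03) or aged replicate 1 (0.04) for astrocytes. They also did so without aged replicate 2 for cytokines (-0.07), and without adult replicate 3 (-0.0136) or aged replicate 2 (-0.0077) for homeostatic microglia. Over these omissions the medians lay between -0.17 and 0.02 for MHC class I, between -0.07 and 0.14 for cytokines and between -0.33 and -0.0116 for perivascular macrophages. Of the lymphocyte list only Cd4 and Lck were tested, too few for camera, and Cd4 was called when adjusted over the list alone.

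Leaving out 1 rat brought several of these lists past the threshold of camera with the preset correlation. That test also called between 8 and 26 lists in splits of the 6 libraries that mixed the ages. An estimated correlation and fry were not run without a library, so these calls are weak evidence. Homeostatic microglia were called higher without adult replicate 2 (adjusted p = 0.00390) or aged replicate 3 (0.00565), and activated microglia without aged replicate 3 (0.0348). Lower calls appeared for interferon response without adult replicate 1 (0.00507), aged replicate 1 (0.00119) or aged replicate 2 (0.0213), for complement without aged replicate 2 (0.0332), for astrocytes without adult replicate 3 (0.00274) and for reactive astrocytes without aged replicate 2 (0.00728). With log2(FPKM + 1) reactive astrocytes were also called lower (camera adjusted p = 0.0421).

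Immediate early genes and genes of acetylcholine and monoamine receptors were called higher in aged rats. Immediate early genes, which neurons induce within minutes of firing, had 22 of 24 members higher (median 0.26, camera adjusted p = 1.93e-07, adjusted p = 0.469 with an estimated correlation), with 0 called when adjusted over the list alone. Fos averaged 5.05 ± 1.78 CPM in adult and 8.84 ± 2.08 CPM in aged rats, Fosb 6.87 ± 1.27 and 12.3 ± 3.28 CPM and the phosphatase gene Dusp1 19.3 ± 4.24 and 33.5 ± 6.42 CPM. Bdnf, a growth factor induced by activity, averaged 42.7 ± 10.3 and 49.5 ± 4.12 CPM. DESeq2 called 2 members of this list when adjusted over the list alone. An exact two-sided permutation test of the list score gave p = 0.1, the smallest possible. Acetylcholine and monoamine receptor genes had 19 of 20 members higher (median 0.38, camera adjusted p = 6.25e-05, adjusted p = 0.581 with an estimated correlation), with the nicotinic receptor gene Chrna7 at 49.4 ± 10.3 and 62.3 ± 7.34 CPM and the serotonin receptor gene Htr2a at 0.476 ± 0.380 and 1.43 ± 0.377 CPM. The median of that list was 0.69 without adult replicate 2. Its scores overlapped between the ages, with p = 0.3 by exact two-sided permutation test.

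Synaptic vesicle and release genes had 20 of 26 members higher (median 0.13, camera adjusted p = 0.00103, adjusted p = 0.629 with an estimated correlation). Sv2c averaged 18.2 ± 0.599 CPM in adult and 25.3 ± 2.24 CPM in aged rats and Unc13b, which primes vesicles, 34.1 ± 3.52 and 42.8 ± 4.61 CPM. Unc13b overlaps Tmsb4xl2 in the GRCr8 annotation, which leaves its count uncertain where reads were not assigned by strand. The call ended without adult replicate 1 (adjusted p = 0.115, median 0.08) or aged replicate 1 (0.223, median 0.03), and the median was 0.22 without adult replicate 2 and 0.265 without aged replicate 2. The vesicle score did not follow age alone. It was below 0 in adult replicates 1 (-0.249) and 3 (-0.171) and aged replicate 2 (-0.0582), and above 0 in the other libraries. GABAergic interneuron genes had 17 of 20 higher (median 0.22, camera adjusted p = 0.00198, adjusted p = 0.629 with an estimated correlation), with the neuropeptide gene Vip at 19.6 ± 5.14 and 31.0 ± 4.12 CPM and Pvalb, which was lower, at 117.9 ± 11.0 and 91.9 ± 18.8 CPM. That call ended without adult replicate 3 (adjusted p = 0.335, median 0.10) or aged replicate 1 (0.112, median 0.14). Markers of the neighbouring neocortex, which also include Vip, had 11 of 15 higher (median 0.115, camera adjusted p = 0.0209, adjusted p = 0.629 with an estimated correlation), with Ctgf at 23.0 ± 8.87 and 45.2 ± 9.66 CPM. The neocortex call ended without adult replicate 1 (adjusted p = 0.393), aged replicate 1 (0.194) or aged replicate 2 (0.0542), with medians of 0.02, 0.04 and 0.04 in turn, and the median was 0.35 without adult replicate 2 and 0.22 without aged replicate 3. It also ended with the surrogate variable (adjusted p = 0.13, median 0.09). In these 4 lists of receptors, vesicles, interneurons and neocortex, 0 members were called when adjusted over the list alone, but 1 vesicle gene was called without adult replicate 2 and 3 neocortex genes with DESeq2.

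Lists of neurogenesis and of hippocampal fields were not called. Newborn neuron genes had 12 of 16 members higher (median 0.12, adjusted p = 0.407), with Sox4 at 20.4 ± 2.01 CPM in adult and 15.5 ± 1.62 CPM in aged rats, Cd24 at 79.0 ± 9.86 and 65.8 ± 2.77 CPM and the immature neuron marker Dcx at 26.6 ± 10.5 and 32.0 ± 4.23 CPM. The newborn neuron median was 0.04 without adult replicate 3, 0.07 without aged replicate 2, 0.19 without adult replicate 1, 0.21 without adult replicate 2, 0.25 without aged replicate 1 and 0.18 without aged replicate 3. Medians were -0.15 for dentate gyrus granule cells (adjusted p = 0.559), -0.09 for CA1 pyramidal cells (0.950), -0.07 for CA2 and CA3 pyramidal cells (0.501) and -0.02 for the neighbouring thalamus (0.853). The camera direction was higher for the dentate gyrus and CA1 lists, against their medians and means. The neighbouring striatum and amygdala had a median of 0.22 (adjusted p = 0.0785), and were called higher without adult replicate 2 (0.00390) or aged replicate 1 (0.0353), with log2(FPKM + 1) (0.0292) and with the surrogate variable (0.0432). Dentate genes were called higher without adult replicate 3 (adjusted p = 0.00171, median 0.19), the library with the highest dentate score (0.484). The CA1 median was -0.44 without aged replicate 1, -0.28 without adult replicate 1 and between -0.0621 and -0.03 without each other library. The CA2 and CA3 median lay between -0.25 (without adult replicate 2) and 0.09 (without aged replicate 2) and was also above 0 without adult replicate 1 (0.06). The thalamus median lay between -0.20 (without adult replicate 1) and 0.07 (without adult replicate 2).

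The remaining lists were not called, and 0 of their members were called when adjusted over the list alone. In other settings 1 member was called in the clock list (DESeq2, FPKM values, or without genes that differed at least 8-fold between libraries of one age). In the insulin and IGF list it was 1 without adult replicate 2, without a filter, with DESeq2 or the surrogate variable, and without those 8-fold genes. Medians were 0.13 for ionotropic glutamate receptors (adjusted p = 0.156), 0.08 for postsynaptic scaffolds (0.504), 0.06 for GABA-A receptors (0.329), -0.05 for the nuclear genes of the mitochondrial respiratory chain (0.400), 0.04 for cholesterol synthesis (0.600) and -0.06 for antioxidant genes (0.347). They were -0.12 for senescence and DNA damage (adjusted p = 0.108), 0.06 for the circadian clock (0.297), 0.0450 for glucocorticoid response (0.587), 0.00563 for insulin and IGF signalling (0.950), -0.0008 for amyloid and tau (0.642), -0.0022 for lysosome and autophagy (0.950) and 0.0031 for heat shock and chaperones (0.950). Median, mean and camera direction differed in sign for lysosome, heat shock and insulin lists. The calls that follow used camera with the preset correlation only. Leaving out 1 library brought calls of higher values for glutamate receptors (adjusted p = 0.0156 without adult replicate 2 and 0.0139 without aged replicate 2), cholesterol synthesis (0.0249 without aged replicate 3) and the clock (0.0182 without adult replicate 2). It brought calls of lower values for the respiratory chain (adjusted p = 0.00493 without adult replicate 2 and 0.00608 without aged replicate 2), antioxidant genes (0.0347 without aged replicate 2) and senescence (0.0157 without adult replicate 3 and 0.0259 without aged replicate 2). Medians crossed 0 without adult replicate 1 for postsynaptic scaffolds (-0.02), the respiratory chain (0.05), senescence (0.02) and the clock (-0.04), and without aged replicate 3 for the respiratory chain (0.04) and glucocorticoid response (-0.13). Without aged replicate 1 they did so for postsynaptic scaffolds (-0.02), glutamate receptors (-0.00351), GABA-A receptors (-0.06) and cholesterol synthesis (-0.06), and the glucocorticoid median was 0.23. Medians of the insulin, amyloid, lysosome and heat shock lists took both signs over these omissions, between -0.0576 and 0.0807. The genes encoded by the mitochondrial genome were not analysed here.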

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

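The block for liver transcripts, the surrogate variable and the omission of genes that differ between libraries of one age were chosen only after the results were seen. The count of 0 genes called by edgeR (503 at an unadjusted p under 0.05) was also 0 with RLE, upper-quartile and library size scaling, without a filter, with at least 1 CPM in 3 libraries, with robust quasi-likelihood, limma-voom, log2(FPKM + 0.1), unfiltered FPKM and the 3 added settings. It was 32 with DESeq2 (13 higher, 19 lower) and 1 with log2(FPKM + 1) (1 lower), and between 0 and 1 when leaving out a library. The 169 genes at an unadjusted p under 0.05 and at least 2-fold became 291 without a filter, 45 with log2(FPKM + 1), 83 with log2(FPKM + 0.1), 41 with unfiltered FPKM, and between 156 and 302 without a library. The 28 list members called when adjusted over the list alone became 46 with DESeq2, 18 with unfiltered FPKM and between 5 and 31 without a library. The 16 lists called became 0 with an estimated correlation and 0 with fry, which keep the same fold changes and let members of a list vary together. Their medians under both were 1.38 (MHC class II presentation), -0.67 (mature oligodendrocyte and myelin), -0.18 (oligodendrocyte precursor), -0.41 (proliferation), -0.15 (collagen and extracellular matrix), 0.26 (immediate early), 0.13 (synaptic vesicle and release), 0.22 (GABAergic interneuron), 0.38 (acetylcholine and monoamine receptor), -1.99 (choroid plexus), -0.39 (endothelium), -0.57 (pericyte and smooth muscle), -0.47 (meningeal fibroblast), -0.63 (blood and erythroid), 0.12 (neighbouring neocortex), -0.15 (cytosolic ribosome). With at least 1 CPM in 3 libraries the call of the proliferation list ended (median -0.23). With log2(FPKM + 1), reactive astrocytes (median -0.11) and the striatum and amygdala (0.18) were called, and with the surrogate variable the striatum and amygdala (0.14) were called and the neocortex (0.0918) was not. Between 11 and 21 lists were called without a library, 8 of the 16 in every case, and 15 other lists were called in some case. Medians over these omissions, for lists with a call that changed, were -0.0136 to 0.27 (homeostatic microglia), 0.0458 to 0.18 (activated microglia), -0.16 to 0.0259 (complement), -0.21 to 0.0609 (interferon response), -0.14 to 0.0421 (astrocyte), -0.32 to -0.0296 (reactive astrocyte), -0.27 to -0.14 (oligodendrocyte precursor), -0.30 to -0.11 (collagen and extracellular matrix), -0.00351 to 0.23 (ionotropic glutamate receptor), 0.0267 to 0.27 (synaptic vesicle and release), 0.0956 to 0.31 (GABAergic interneuron), -0.17 to 0.0523 (mitochondrial respiratory chain, nuclear), -0.0631 to 0.15 (cholesterol synthesis), -0.15 to -0.00929 (antioxidant and oxidative stress), -0.24 to 0.0166 (senescence and DNA damage), -0.0419 to 0.17 (circadian clock), -2.75 to -0.0185 (choroid plexus), -0.43 to 0.69 (ependyma and motile cilia), -0.81 to -0.19 (blood and erythroid), -0.36 to 0.19 (dentate gyrus granule cell), 0.0704 to 0.56 (neighbouring striatum and amygdala), 0.0192 to 0.35 (neighbouring neocortex), -0.37 to -0.0379 (cytosolic ribosome). Of 63 genes taken by the naming rule, 17 passed the threshold in some alternative and 3 changed direction. Without a library the log2 fold change lay between -0.26 and 0.0873 for Gfap (0.02 without adult replicate 3, 0.05 without aged replicate 3), between -0.19 and 0.26 for C3 (-0.09 without aged replicate 2) and between -4.93 and 0.33 for Ttr. Where a change is not explained by fewer samples, fewer genes or the correlation allowed, the cause was not tested.

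With the replicate block 0 genes and 18 lists were called, and 192 genes passed the unadjusted threshold at 2-fold. Homeostatic microglia (median 0.16) and the striatum and amygdala (0.28) were called under the block, which changed no other call of a list. Of members called when adjusted over the list alone, it took MHC class II presentation from 6 to 0, activated microglia and reactive astrocytes from 1 to 0 each, collagens from 2 to 4, the choroid plexus from 0 to 1 and the neocortex from 0 to 3. The labels give no meaning to a shared number, although both libraries numbered 1 were low in liver transcripts. The deviations of libraries with the same number from the group means correlated at -0.0152, -0.0570 and 0.0865 for numbers 1, 2 and 3. The highest correlation of each adult library with an aged library of another number was 0.118, 0.0602 and 0.0106. Only adult replicate 3 thus correlated best with the aged library of its own number.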

Other observations

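The counts over other splits of the libraries, the test of myelin without adult replicate 1, the test of vessels against collagens and the tests of the narrowed set of switching genes were chosen only after the result was seen. The tests of gene length, of held-out liver and muscle genes and of the full set of switching genes were not.

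The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. With 0 genes called by edgeR in the real split (503 at an unadjusted p under 0.05, 32 called by DESeq2), all 10 splits give at least as many by construction, as they do for calls in a single direction, so these counts decide nothing (highest other 1 for both). At an unadjusted p under 0.05 and at least 2-fold, 3 splits, the real one included, gave at least 169 genes (highest other 314). At least 16 lists were called in 4 splits (highest other 26), and at least 32 genes by DESeq2 in 4 splits (highest other 673), the real split included in both. The split that set adult replicates 1 and 3 and aged replicate 2 against the rest gave those 673 genes and 2104 at an unadjusted p under 0.05 by edgeR. It is named as the largest of the 10 splits, and edgeR called 1 gene in it. Its division of the libraries appeared in some list scores, named here for their values. The ribosome score was 0.234 and 0.134 in adult replicates 1 and 3, 0.317 in aged replicate 2 and below 0 in the others. The synaptic vesicle score was below 0 in those 3 and above 0 in the others, while the myelin score did not follow the division. The surrogate variable was above 0 in those 3 alone. The cause of this structure, which mixes the ages, was not tested.

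Liver and skeletal muscle genes differed between libraries of one age. Before their values were seen, further genes of each tissue were listed: 22 of 28 liver genes (78.6%, 6.67% by chance, exact one-sided binomial p = 3.39e-21) were lower in replicate 1 of both ages than in each other library, and 13 of 17 muscle genes (76.5%, 3.33% by chance, exact one-sided binomial p = 1.32e-16) were highest in adult replicate 3 and lowest in aged replicate 2. Genes of a tissue move together, so these p-values overstate the evidence. A candidate explanation is RNA of those tissues, or reads of libraries of those tissues assigned to these, and no value separates the 2 sources. With the libraries low in liver transcripts as a block, edgeR called 0 genes and camera 16 lists.

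The lower myelin list may reflect age, tissue beside the hippocampus, such as white matter, in some dissections, or both. Without adult replicate 1, the library with the highest score, the median was -0.489 and 18 of 19 members were lower, but the scores of aged replicate 3 (0.040) and adult replicate 3 (0.0254) overlap, which keeps that explanation open. Another split of the libraries gave a median about as large as the -0.67 of the split by age. It set adult replicates 1 and 2 and aged replicate 3 against the rest, which were lower (median -0.669), and is named for that value. The tables argue against gene length as the cause: with the trend on length removed the median was -0.652, against -0.67 before. The difference between ages was not tested against dissection, and no biological explanation was tested.

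Among 11536 genes with a mean of at least 5 CPM, 64 differed at least 8-fold between libraries of one age. A gene whose switch lined up with age, such as Polr2i might be, could not enter this set. A locus identifier in place of a symbol was carried by 26.6% of the 64 and 4.42% of other genes (odds ratio 5.16, 95% interval 2.91 to 9.14), so reads shared with uncharacterised or duplicated loci may be a source. The test of an adjoining protein-coding gene in GRCr8 (odds ratio 0.691, 0.373 to 1.28) met the bound set in advance against that explanation. It is void, since only 73.4% of the 64 had a match, a share looked at only after the odds ratio had been seen, so the explanation stays open. After these values had been seen, the 18 liver and muscle genes among the 64 were left out: the odds ratios became 8.50 (4.57 to 15.8) for locus identifiers and 1.37 (0.661 to 2.85) for an adjoining gene, again void with 63.0% of 46 matched. The odds ratio for an adjoining gene moved across 1 with the choice of set.

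Collagen I and III genes (Col1a1, Col1a2 and Col3a1) were chosen after their values were seen, and Col1a1 overlaps Sgca in the GRCr8 annotation. Their aged minus adult difference relative to the endothelium list was -1.42 on the log2 scale (exact two-sided permutation p = 0.1, the smallest possible), with libraries between 0.52 and 0.89 in adult rats and between -1.32 and -0.08 in aged rats. A test on genes picked for this difference decides nothing about less vessel and meningeal tissue in the aged dissections.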
